A study of Homo sapiens with 12 samples.

How the data were processed

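The data are small RNA sequencing libraries of MDA-MB-231 cells and of the EVs they released, 12 in all, with 2 replicates in each of 6 groups. Per the labels' protocols, cells were grown in medium with 10% fetal bovine serum, and conditioned medium was collected after 24 h in serum-free medium with 1% bovine serum albumin. EVs were pelleted by ultracentrifugation after pre-clearing spins, washed and collected together with the cells that made them. RNA was extracted with Trizol from cells and with its liquid-sample form from EVs. Each sample was made into a library by a protocol that depends on a 5′ monophosphate, and small RNAs were size-selected and sequenced on a Genome Analyzer IIx. Knockdown of RAB27A used a lentiviral short hairpin RNA and its control an empty vector; the miR-122 knockout used 2 guide RNAs. The labels number the replicates without saying whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

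The deposited values are counts per mature miRNA, whole numbers that were not normalized. Per the submitters' processing notes, cutadapt and Bowtie were used with genome build hg19, with no version given; the miRNA annotation, the number of mismatches and the treatment of reads that match several miRNAs are not given in the sources used here. Among miRNAs with at least 50 counts in all, the deposited counts form 9 sets with identical values in all libraries. Examples are miR-199a-3p and miR-199b-3p or miR-365a-3p and miR-365b-3p. Sets among miRNAs with fewer counts were not looked for. Members of such sets share their reads and count as separate entries in the totals of calls. Close family members that differ by few bases can share reads as well. No molecular identifiers are recorded, so intervals and limits from counts cover counting error only.

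Total counts per library ran from 164656 to 11840597. The level of a miRNA is given as counts scaled to a common library total (CPM), with the mean and SD over 2 replicates, 95% exact Poisson intervals where single libraries are given, and a limit of 3 counts where none was seen, over the group's summed total. Folds against a group with no count are bounds from that limit. For miRNAs with 1 to 3 counts in a group the ratio of pooled CPM is given with an exact binomial 95% interval.

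The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors, robust dispersion estimates, miRNAs kept by filterByExpr and Benjamini-Hochberg adjustment at 0.05, and each adjusted p of a named miRNA comes from it. Comparisons between lines were fitted on the 6 libraries of a fraction, so that cells and EVs do not share scaling factors or one estimate of the spread (613 miRNAs in cells, 488 in EVs). Comparisons of EVs with cells and the interactions were fitted on all 12 libraries (574 miRNAs). The SE beside the log2 fold change of a miRNA is the size of that change over the square root of the test's F value. It is not a separately fitted standard error. With few counts it can be smaller than counting error alone would give. On simulated counts with 200 changed miRNAs per comparison, 93.8% of those changed 4-fold were recovered for the knockdown in cells, 98.2% for the knockout in cells, 73.7% for the knockdown in EVs, 100% for the knockout in EVs and 98.5% for EVs against cells, with 1.97% to 4.72% false among the calls. For 2-fold changes recovery was 68.3%, 77.5%, 53.7%, 78.2% and 86.9%. Each comparison had a single simulation with the direction of each change drawn at random. These rates therefore do not cover changes mostly in a single direction, a larger share of changed miRNAs or a trend with GC content.

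The design, the tests, the alternatives, the lists and the rule for named miRNAs were fixed before the data were examined. The text names the arms of miR-122 and of its antisense miR-3591, where tested, in each comparison except the mean over lines. It also names the miRNAs past the threshold with the largest changes whose libraries did not overlap and whose mean level was at or above the median, up to 10 per direction for line comparisons, 15 for the mean over lines and 5 for single-line EV comparisons and interactions. The rule further takes the most abundant miRNAs and up to 4 of the most abundant members per list. Of the abundant miRNAs and list members the text names a subset, picked after their values were seen. Also chosen after their values were seen were the count of C19MC sequences with identical ones taken once, the ratios with counting intervals, and the miRNAs outside the rule: miR-15a-5p and miR-516a-5p in knockdown cells, miR-887-3p, miR-105-5p and miR-767-5p, and any other.

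In all, 25 lists were fixed: the let-7, miR-200, miR-29, miR-30, miR-15/16, miR-99/100 and miR-125, miR-181, miR-34 and miR-449, miR-130 and miR-301, and miR-148 and miR-152 families; the miR-17-92 clusters, the cluster of miR-183, miR-96 and miR-182, the miR-23/24/27 and miR-221 and miR-222 clusters; miR-146 with miR-155; the clusters at 14q32, at 19q13 (C19MC) and the X-linked miR-506 cluster; annotated miRNAs known to overlap other abundant RNAs; and markers of liver, blood cells and serum, muscle, nervous system, endothelium (miR-126) and stroma (miR-143, miR-145, miR-199 and miR-214). Each list with at least 3 tested members was tested by camera on log2 CPM with a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Over the 10 comparisons 34 of 218 list tests passed with the preset correlation and 6 with the estimated one: 14q32 and stroma in control EVs over control cells and in both interactions.

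GC content was taken from the side of the annotated hairpin that holds the miRNA (GENCODE v29, GRCh38), available for all tested miRNAs; it is not that of the mature sequence. Guides were placed by exact match to the same build. For comparisons that share controls, unchanged groups were simulated 20 times against those controls.

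Alternatives were RLE size factors, total counts, DESeq2 1.42.0, limma-voom, no filter, a filter of 10 CPM in 2 libraries, the replicate number as a block, each library left out in turn, the 5 most abundant miRNAs or the fragments of other RNAs left out, and fits on other sets of libraries. Chosen after seeing the data were a restriction of EV comparisons to miRNAs at 10 CPM or more in a cell group, thinning of libraries to the shallowest, the mean over lines without each line and a correction for the trend with GC content. No deposited library was left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.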

Results

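Small RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer line, and from the extracellular vesicles (EVs) those cells released into their medium. Each of 3 lines gave cells and EVs with 2 libraries each, so that 12 libraries fell into 6 groups: a control line carrying an empty vector, a line with a short hairpin RNA against RAB27A, and a line in which the miR-122 gene was edited with CRISPR-Cas9. RAB27A is a small GTPase that docks multivesicular bodies at the plasma membrane, and miR-122 is a microRNA made mainly by hepatocytes. The table gave a count for each of 2588 mature human miRNAs, 869 of which had no count in any library. Control cells held 11840597 and 11066570 counts, RAB27A knockdown cells 3159478 and 3140610, and miR-122 knockout cells 10169004 and 9836680. Control EVs held 2387336 and 2596391 counts, knockdown EVs 164656 and 170366, and knockout EVs 3754673 and 3166760. The knockdown EV libraries were the shallowest, and 1 count was worth 6.07 and 5.87 CPM there, CPM being counts scaled to a common library total, against 0.0845 and 0.0904 in control cells. Between 485 and 1189 miRNAs were detected per library. miR-100-5p was the most abundant miRNA in 10 libraries, with 27.7% to 49.5% of the counts, and miR-21-5p led in the knockdown EVs with 23.9% and 22.9%. Over the miRNAs with at least 20 counts in a group, 195 in knockdown EVs to 573 in control cells, replicates correlated at 0.989 to 0.9973 in log2 CPM. Over 641 miRNAs with at least 50 counts in all, they correlated at 0.927 in knockdown EVs and 0.992 to 0.998 in the other groups. On the first sets they differed by more than counting noise in each group, with a chi-square per degree of freedom from 8.75 in knockdown EVs to 211 in knockout cells, so no pair was treated as a single library. Over the 641 miRNAs, libraries of knockout EVs correlated more closely with control cells (mean 0.959) than those of control EVs did (0.866). The knockout EVs correlated less closely with the knockout cells (0.942) than with the control cells. RAB27A is protein-coding, and its level was not measured by these libraries.

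The target of the knockout was read in every library first. miR-122-5p had 5 and 4 counts in the control cells, 0.392 CPM ± 0.043 (SD, n = 2), and no count in either knockout cell library, which allows a level of up to 0.15 CPM over the group. Control EVs held 790 and 651 counts of it, 291 CPM ± 56.7 (SD, n = 2), with 95% exact Poisson intervals of 308 to 355 CPM and 232 to 271 CPM. Knockout EVs held 4 and 3 counts, 1.01 CPM ± 0.0834 (SD, n = 2). The knockdown line differed in both fractions: its cells held 39 and 40 counts, 12.5 CPM ± 0.278 (SD, n = 2), and its EVs 7 and 5 counts, 35.9 CPM ± 9.31 (SD, n = 2). By edgeR's quasi-likelihood test, miR-122-5p was lower in knockout than in control EVs (log2 fold change −7.72, SE 0.30, adjusted p = 2.84e-10) and at least 2.61-fold lower in knockout than in control cells (adjusted p = 0.00817), a bound set by the 9 counts of the control cells. It was higher in knockdown than in control cells (log2 fold change 4.95, SE 0.40, adjusted p = 3.4e-09) and lower in knockdown than in control EVs (−3.14, SE 0.35, adjusted p = 8.6e-06). The fall of miR-122-5p in knockout EVs cannot be put down to the edit alone. The fixed list of blood cell and serum miRNAs, which were not edited, fell there by a median of −6.9 on the log2 scale (−6.61 with bounds). The other arm, miR-122-3p, had 1 count in all 12 libraries, in a knockdown cell library. The antisense miR-3591-5p had 1 count, in a control EV library, and miR-3591-3p had none. Those arms were not detectable at this depth and were not tested.

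**Figure D1:**
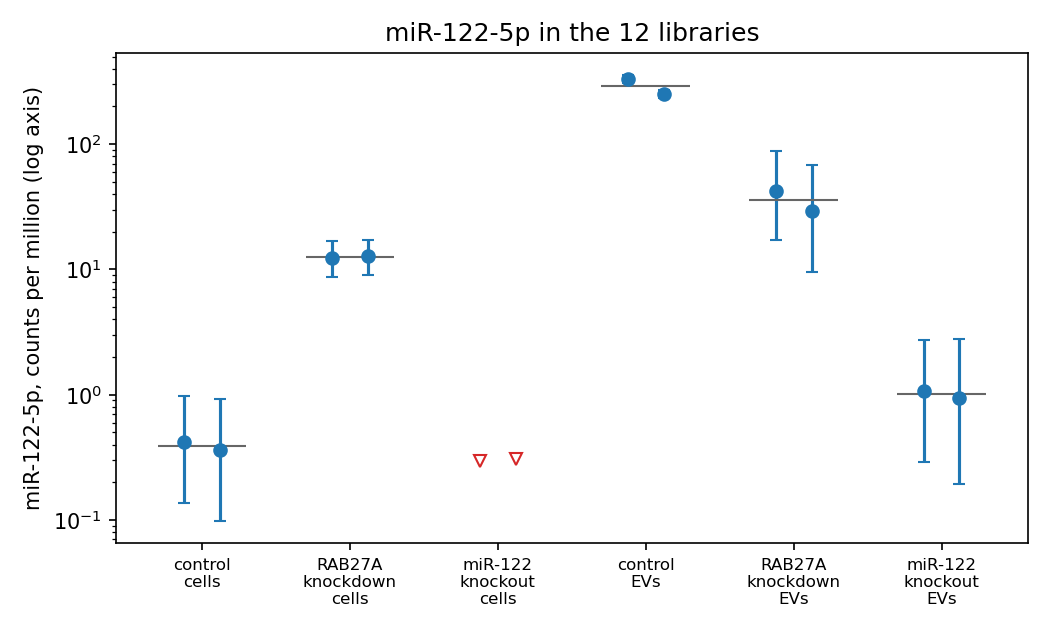
miR-122-5p in CPM on a log axis for each of the 12 libraries, with points for libraries, bars for 95% exact Poisson intervals and grey lines for group means. Open triangles mark the limit that 3 counts would set in the knockout cell libraries, which had no count; the control EVs sit at 331 and 251 CPM, above the other 10 libraries.

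Both guide sequences were placed on the miR-122 hairpin, which lies on the plus strand of chromosome 18 at 58451074 to 58451158 in GRCh38 (GENCODE v29) and is 85 nt long. CACACTAAATAGCTACTGCT matched the sense strand at hairpin positions 62 to 81 (58451135 to 58451154), and CACACTCCACAGCTCTGCTA matched the antisense strand at positions 4 to 23 (58451077 to 58451096). Both matches were followed by AGG, a motif that Cas9 from Streptococcus pyogenes recognises.

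The first comparison asked how the RAB27A knockdown line differed from the control line inside the cells. The miRNAs of 2 genomic clusters stood far higher in the knockdown cells. From the miR-106a-363 cluster on the X chromosome, miR-363-3p was 179-fold higher (log2 fold change 7.48, SE 0.25, adjusted p = 8.77e-15), at 165 CPM ± 2.89 against 0.907 ± 0.389 (SD, n = 2 each), and miR-20b-5p rose by 4.82 on the log2 scale (SE 0.22). From the let-7c, miR-99a and miR-125b-2 cluster on chromosome 21, miR-125b-2-3p rose by 6.70 (SE 0.25), miR-99a-5p by 4.40 (SE 0.13) to 7686 CPM ± 627 (SD, n = 2), and let-7c-5p by 3.34 (SE 0.17). miR-146a-5p, a repressor of NF-kappaB signalling, rose from 4769 CPM ± 29.5 to 53400 ± 1978 (log2 fold change 3.50, SE 0.12, adjusted p = 5.32e-15). miR-34a-5p, a transcriptional target of p53, was 37-fold lower (log2 fold change −5.21, SE 0.20), at 6.51 CPM ± 0.197 against 244 ± 7.64 (SD, n = 2 each).

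Other miRNAs that rose in the knockdown cells were miR-95-3p (log2 fold change 5.29), miR-135b-5p (3.87), miR-135b-3p (3.70) and miR-218-1-3p (3.54). Those that fell included miR-653-3p (−4.77), miR-3681-5p (−4.37), miR-577 (−4.02), miR-27b-5p (−3.47), miR-335-3p (−3.20), miR-149-5p (−3.10), miR-23b-5p (−3.05), miR-33b-3p (−2.87) and miR-210-5p (−2.63). Of the 12 tested members of the miR-15/16 family, which represses cell cycle genes, 11 fell and none rose, also 11 when adjusted over the list alone; miR-15a-5p changed by −1.01 (SE 0.12) and miR-424-5p by −0.83 (SE 0.12). The camera test of that family gave adjusted p = 0.00183, and adjusted p = 0.522 with an estimated correlation. Of the 13 listed entries of the placental cluster on chromosome 19 (C19MC), 9 rose and none fell (10 adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.522 with an estimated correlation), led by miR-516a-5p at 1.63 (SE 0.13). Several of those entries repeat the counts of 1 sequence, and of 7 distinct ones 4 rose. All 3 tested entries of the liver list rose (3 adjusted over the list alone; camera adjusted p = 0.0352, adjusted p = 0.522 with an estimated correlation): miR-122-5p, miR-192-5p at 1.10 (SE 0.13) and miR-194-5p at 1.22 (SE 0.14). The 2 most abundant miRNAs did not pass: miR-100-5p stood at −0.14 (SE 0.12, adjusted p = 0.358) and miR-21-5p at 0.16 (SE 0.11, adjusted p = 0.221). miR-100-5p passed without filtering (−0.37), in a fit on the 4 libraries compared (−0.11) and without knockout cell replicate 2 (−0.14). miR-21-5p passed with RLE size factors (0.29), DESeq2 (0.29), the GC correction (0.25), the 4 libraries alone (0.20) and without knockout cell replicate 1 (0.19) or 2 (0.16). In all, 330 of 613 tested miRNAs passed a false discovery rate of 0.05, 149 higher and 181 lower in the knockdown cells, and 97 of them differed at least 4-fold. The knockdown was a single line, so these differences are between lines; without knockdown cell replicate 1 the count was 196 and without replicate 2 it was 218.

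The second comparison set the miR-122 knockout cells against the control cells. miR-454-3p fell from 6306 CPM ± 33.3 to 299 ± 15 (SD, n = 2 each; log2 fold change −4.05, SE 0.12, adjusted p = 7.32e-16). miR-148a-3p fell from 5560 CPM ± 27.8 to 287 ± 18.2 (−3.92, SE 0.14), and miR-20a-5p, a member of the growth-promoting miR-17-92 cluster, from 3923 ± 124 to 314 ± 46.4 (−3.31, SE 0.12). miR-590-3p (−5.06, SE 0.23), miR-335-3p (−4.95, SE 0.18), miR-374b-3p (−4.41, SE 0.25), miR-374a-5p (−3.75, SE 0.15) and miR-374a-3p (−3.58, SE 0.14) also fell. miR-125b-2-3p and miR-363-3p had no count in the knockout cells and were at least 6.71-fold and at least 6.05-fold lower. miR-20b-5p had 3 counts there against 68, a 19.8-fold lower share (95% counting interval 6.49 to 98.4).

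Among the miRNAs that rose in the knockout cells, miR-326 changed by 3.88 (SE 0.29), miR-193b-3p by 2.88 (SE 0.22) and miR-146a-5p by 2.69 (SE 0.12, adjusted p = 7.455e-14), to 24210 CPM ± 910 (SD, n = 2). The most abundant miRNA, miR-100-5p, rose by 0.90 (SE 0.12). All 13 tested C19MC entries rose, also 13 adjusted over the list alone (camera adjusted p = 1.67e-06; adjusted p = 0.473 with an estimated correlation). Among them were miR-516a-5p (3.10, SE 0.13), miR-1283 (2.74, SE 0.22), miR-522-3p (1.87, SE 0.15) and a sequence shared by 6 entries with identical counts, among them miR-518e-5p, miR-519a-5p, miR-519b-5p, miR-519c-5p and miR-522-5p (2.68, SE 0.26). With each sequence counted once, 7 of 7 rose (camera p = 2.58e-05, and p = 0.0222 with an estimated correlation). These 2 p-values were not adjusted over lists, so they cannot be set beside the adjusted ones above. Of the miR-15/16 family, 9 of 12 members fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.00943, adjusted p = 0.473 with an estimated correlation), with miR-16-5p at −2.81 (SE 0.12) and miR-424-5p at −2.08 (SE 0.12). Of the miR-181 family, 6 of 10 rose and none fell (7 adjusted over the list alone; camera adjusted p = 0.0239, adjusted p = 0.473 with an estimated correlation), with miR-181a-5p at 1.21 (SE 0.11); with total counts in place of TMM factors its adjusted p was 0.0542. All 3 tested members of the list of miR-146 and miR-155 rose (3 adjusted over the list alone; camera adjusted p = 0.0155, adjusted p = 0.473 with an estimated correlation). In all, 382 of 613 miRNAs passed, 170 higher and 212 lower, and 113 differed at least 4-fold. With total counts the higher ones made up 32.4% of the calls against 44.5% with TMM factors. The log2 fold changes correlated with the GC content of the hairpin side that holds each miRNA (Spearman rho 0.418 across 613 miRNAs, which are not independent replicates). The deviations of each library from the mean of all 12 libraries were also ranked against GC content. Their rank correlation was 0.339 and 0.313 in the knockout cells but −0.142 to 0.0508 in the other 10 libraries. These values are relative, since the knockout cells enter that mean.

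**Figure D2:**
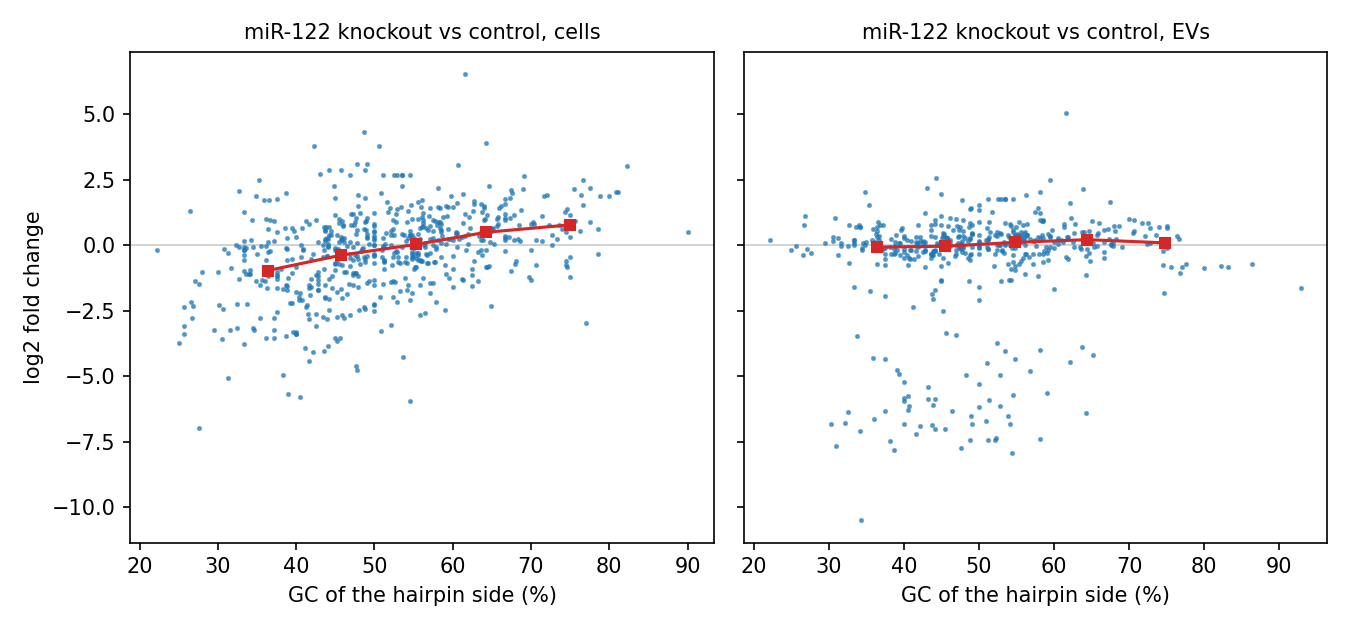
Log2 fold change of miR-122 knockout against control (vertical axis) by the GC percent of the hairpin side that holds the miRNA (horizontal axis), in cells on the left and EVs on the right; each dot is a miRNA and the red squares join medians of bins of GC content that hold at least 20 miRNAs. The medians run from −0.97 to 0.78 in cells (Spearman rho 0.418) and from −0.07 to 0.21 in EVs (0.149), where values of miRNAs with no count in a group are fitted ones.

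In EVs, the knockdown line was compared with the control line on 488 tested miRNAs. The difference was led by miRNAs known from blood cells and connective tissue that were abundant in control EVs and absent or rare in knockdown EVs. miR-199a-3p and miR-199b-3p, a single mature sequence known from fibroblasts, stood at 454 CPM ± 24.6 (SD, n = 2) in control EVs and had no count in knockdown EVs (at least 50.7-fold lower). The myeloid miR-223-3p was at least 38.3-fold lower, the erythroid miR-144-5p at least 34-fold lower and the lymphoid miR-150-5p at least 29.3-fold lower. miR-143-3p, known from smooth muscle, fell from 2609 CPM ± 93 to 110 ± 1.56 (log2 fold change −4.68, SE 0.27, adjusted p = 5.42e-08), and the erythroid miR-451a from 4484 ± 718 to 44.5 ± 20 (−6.76, SE 0.80, adjusted p = 0.00142), a call that was lost without knockdown EV replicate 2 (−7.55). Of the 10 tested entries of the fixed list of blood cell and serum miRNAs, 9 fell and none rose (9 adjusted over the list alone; camera adjusted p = 0.00194, adjusted p = 0.73 with an estimated correlation). All 8 tested stroma entries fell (8 adjusted over the list alone; camera adjusted p = 0.00186, adjusted p = 0.325 with an estimated correlation), as did both arms of the endothelial miR-126, miR-126-3p at −2.96 (SE 0.18). Of 34 tested members of the imprinted cluster at 14q32, 23 fell and none rose (25 adjusted over the list alone; camera adjusted p = 2.9e-09, adjusted p = 0.325 with an estimated correlation), among them miR-379-5p with 3 counts against 1354, a 30.3-fold lower share (95% counting interval 10.4 to 147). With miRNAs at 0 counts set to their bounds, the median log2 fold change was −5.17 for the blood list, −4.42 for stroma and −1.44 for 14q32.

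The miRNAs that were higher in knockdown EVs included several that were higher in the knockdown cells. miR-146a-5p rose from 7419 CPM ± 208 to 90270 ± 11610 (SD, n = 2 each; log2 fold change 3.49, SE 0.12, adjusted p = 5.67e-10), with miR-135b-5p (3.73, SE 0.23), miR-146a-3p (2.42, SE 0.29), miR-181d-5p (2.18, SE 0.24) and miR-99a-5p (2.06, SE 0.12). miR-501-3p, miR-660-5p and miR-362-5p, of a cluster on the X chromosome, rose by 2.44, 1.99 and 1.98. miR-6087 (3.19, SE 0.22) and miR-7704 (2.95, SE 0.20), whose annotated sequences overlap other abundant RNAs, rose as well. miR-100-5p fell by 1.35 (SE 0.09) and miR-21-5p, an abundant oncogenic miRNA, rose by 0.87 (SE 0.09). miR-199b-5p, miR-369-3p, miR-409-5p, miR-155-5p and miR-26a-2-3p had no count in knockdown EVs and were at least 17.9-, 11.3-, 8.29-, 7.83- and 7.42-fold lower. Altogether 226 miRNAs passed, 92 higher and 134 lower, and 114 differed at least 4-fold. With all EV libraries thinned to the shallowest, 137 passed. After a correction for the trend with GC content, an alternative chosen after seeing the data, 55.2% of the calls were higher against 40.7% before.

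Knockout EVs also held far less of the blood and stroma miRNAs than control EVs did. miR-143-3p fell from 2609 CPM ± 93 to 18.7 ± 8.99 (SD, n = 2 each; log2 fold change −6.72, SE 0.23, adjusted p = 1.92e-10) and miR-451a from 4484 ± 718 to 22.5 ± 20.6 (−7.21, SE 0.60, adjusted p = 3.5e-04). miR-144-5p (−7.44), miR-144-3p (−7.43), miR-127-3p (−7.43), miR-142-5p (−7.00), miR-379-5p (−6.99), miR-411-5p (−6.86) and miR-223-3p (−6.81) fell to a like extent, and miR-369-3p was at least 234-fold lower. All 34 tested members of the 14q32 cluster fell (34 adjusted over the list alone; camera adjusted p = 1.58e-21, adjusted p = 0.133 with an estimated correlation), with a median of −5.74 when miRNAs at 0 were set to their bounds. Of the blood list 9 of 10 fell (9 adjusted over the list alone; camera adjusted p = 2.37e-06, adjusted p = 0.364 with an estimated correlation), of the stroma list 8 of 8 (8 adjusted over the list alone; camera adjusted p = 2.17e-06, adjusted p = 0.133 with an estimated correlation), and both miR-126 arms fell, miR-126-5p with a log2 fold change of −4.36 (SE 0.18). The blood list summed to 10710 CPM ± 1160 in control EVs, 217 ± 66.5 in knockdown EVs, 192 ± 48.2 in knockout EVs and 282 ± 9.97 in control cells (SD, n = 2 each).

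Other families moved in the opposite direction in knockout EVs. All 11 tested C19MC entries rose, also 11 adjusted over the list alone (camera adjusted p = 9.84e-06, adjusted p = 0.364 with an estimated correlation). Of 6 distinct sequences 6 rose (camera p = 0.00126, and p = 0.0449 with an estimated correlation), with neither of these p-values adjusted over lists. Among the entries were miR-522-3p at 2.03 (SE 0.21) and miR-516a-5p at 1.74 (SE 0.16). Of the miR-200 family, which maintains the epithelial state, 4 of 6 rose and none fell (5 adjusted over the list alone; camera adjusted p = 0.0329, adjusted p = 0.48 with an estimated correlation), with miR-200a-3p at 1.44 (SE 0.15), miR-429 at 1.42 (SE 0.20) and miR-200b-3p at 1.26 (SE 0.13). Of the miR-181 family 4 of 9 rose and none fell (5 adjusted over the list alone; camera adjusted p = 0.0329, adjusted p = 0.364 with an estimated correlation, and 0.167 with total counts and the preset one). miR-146a-3p (1.95, SE 0.17), miR-455-3p (1.54, SE 0.12), miR-135b-5p (1.34, SE 0.19), miR-664a-3p (1.13, SE 0.19) and miR-146a-5p (1.02, SE 0.11, adjusted p = 7.55e-06) rose, and miR-148a-3p changed by −2.37 (SE 0.15). miR-454-3p, which fell in knockout cells, did not pass in EVs (0.17, SE 0.10, adjusted p = 0.23), though it passed after the GC correction (0.34). Nor did miR-181a-5p (0.26, SE 0.10, adjusted p = 0.0527; it passed with limma-voom). Altogether 201 miRNAs passed, 92 higher and 109 lower, and 75 differed at least 4-fold. The count was 127 without control EV replicate 2, 127 among miRNAs at 10 CPM or more in a cell group, and 76 with libraries thinned to the shallowest. In the thinned libraries miR-135b-5p (1.42) and miR-200b-3p (0.77) did not pass. Higher ones made up 45.8% of the calls with TMM factors, 35.1% with DESeq2 and 19.2% with total counts.

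**Figure D3:**
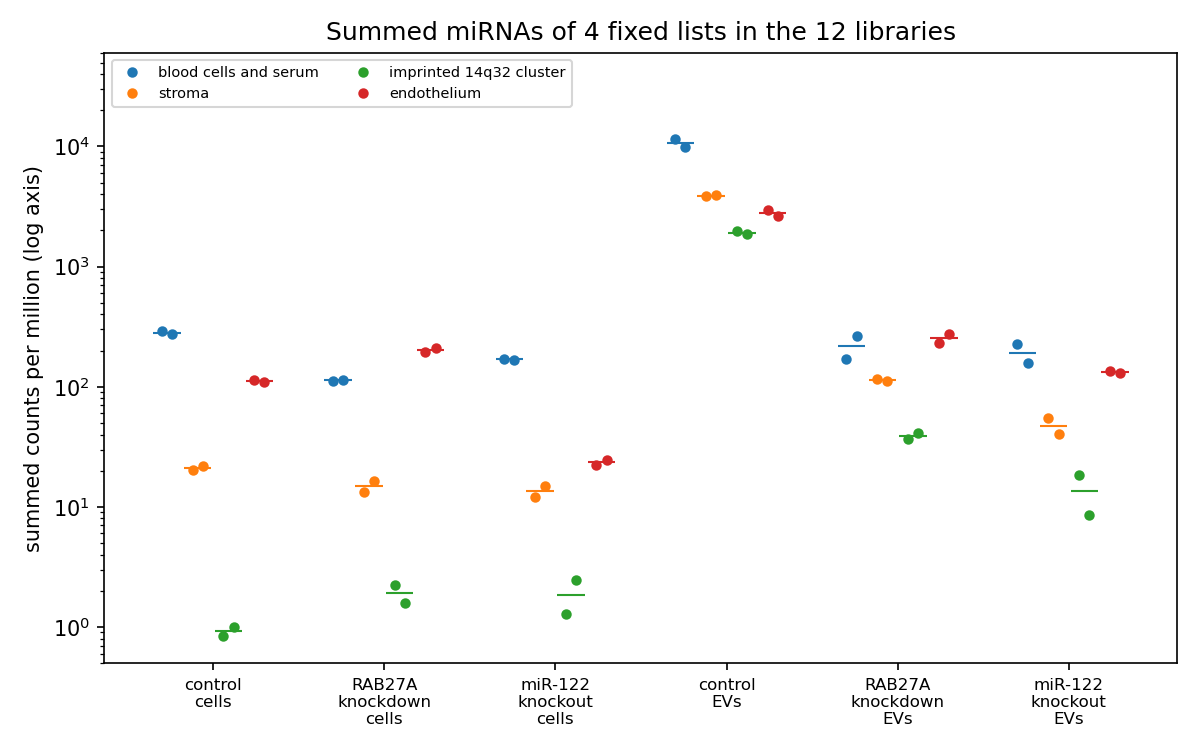
Summed CPM, on a log axis, of the fixed lists of blood cell and serum, stroma, 14q32 cluster and endothelial miRNAs in each of the 12 libraries, with points for libraries and lines for group means. Control EVs stand above the other 5 groups for all 4 lists, at 10710 CPM on average for the blood list.

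The next comparisons asked which miRNAs were enriched in EVs over the cells that released them, collected at the same time. In the control line, blood and stroma miRNAs led the EV-enriched side. miR-451a was higher by 12.85 on the log2 scale (SE 0.77, adjusted p = 5.38e-06) and miR-143-3p by 8.32 (SE 0.21, adjusted p = 8.92e-30). miR-223-3p and miR-150-5p, with no count in control cells, were at least 2620-fold and at least 2000-fold higher. miR-144-3p, with 6895 counts against 3, had a 10600-fold higher share (95% counting interval 3610 to 51200), miR-127-3p a 3470-fold (958 to 28600) and miR-379-5p a 2070-fold higher share (708 to 10100). miR-122-5p was higher by 9.30 (SE 0.28, adjusted p = 6.71e-33), miR-1246 by 6.80 (SE 0.20), miR-126-5p by 5.10 (SE 0.16) and miR-486-5p by 3.16 (SE 0.13). All 38 tested 14q32 members (38 adjusted over the list alone; camera adjusted p = 2.73e-24, adjusted p = 0.0114 with an estimated correlation), all 8 stroma entries (8 adjusted over the list alone; adjusted p = 9.75e-06, and adjusted p = 0.0256 with an estimated correlation), all 10 blood entries (10 adjusted over the list alone; adjusted p = 1.89e-06, and adjusted p = 0.184 with an estimated correlation) and both miR-126 arms were higher in EVs. No 14q32 member and no stroma entry reached 10 CPM in control cells, and 1 blood entry did, miR-486-5p. On the other side, miR-4521 fell by 6.10 on the log2 scale (SE 0.23), from 340 CPM ± 15.2 in cells to 5.49 ± 2.31 in EVs (SD, n = 2 each), and miR-3940-3p (−2.30), miR-1908-5p (−1.95), miR-148a-5p (−1.86) and miR-335-3p (−1.65) were lower in EVs. In all, 308 of 574 miRNAs passed, 177 higher and 131 lower in EVs, and 180 passed when the comparison was limited to miRNAs at 10 CPM or more in a cell group.

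In the knockdown line, 111 of 574 miRNAs passed, 42 higher and 69 lower in EVs. Of those at or above the median mean level whose libraries did not overlap, the highest were miR-6087 (log2 fold change 5.44, SE 0.27), miR-1246 (5.09, SE 0.21), miR-4488 (4.71, SE 0.40), miR-4516 (3.80, SE 0.36) and miR-143-3p (3.71, SE 0.42). The first 4 belong to the fixed list of annotated miRNAs that overlap ribosomal, transfer, small nuclear and other abundant RNAs, of which 12 of 23 were higher and 1 lower (12 and 3 adjusted over the list alone; camera adjusted p = 3.34e-04, adjusted p = 0.0659 with an estimated correlation). All 4 members of the cluster of miR-221 and miR-222 were lower in EVs (4 adjusted over the list alone; camera adjusted p = 0.0351, adjusted p = 0.411 with an estimated correlation), with miR-222-3p at −1.26 (SE 0.12), miR-222-5p at −2.73 (SE 0.26) and miR-221-3p at −0.69 (SE 0.11), which no longer passed with total counts (−0.21) or after the GC correction (−0.33). miR-100-5p changed by −1.76 (SE 0.12), miR-4521 changed by −3.83 (SE 0.41), miR-125a-5p by −2.80 (SE 0.15) and miR-4326 by −2.60 (SE 0.45). miR-21-5p passed with 0.38 (SE 0.11, adjusted p = 0.00846), but not without filtering (0.35) nor on leaving out 10 of the 12 libraries one at a time, all except control cell replicate 1 and knockout cell replicate 1. Those values ran from 0.17 without knockdown EV replicate 1 to 0.33 without control EV replicate 1 or knockout EV replicate 1. miR-26a-2-3p had no count in knockdown EVs (at least 1.56-fold lower), a call lost without either knockdown EV library (−9.17 and −9.18, fitted values that depend on the prior count). It was also lost with total counts, in a fit on the 4 libraries compared and among miRNAs at 10 CPM or more in a cell group. miR-122-5p did not pass (1.04, SE 0.49, adjusted p = 0.145), though it did with total counts (1.51) and after the GC correction (1.40). By comparison, limma-voom passed 215 miRNAs and leaving out the 5 most abundant ones 177. Higher ones were 37.8% of the calls, against 75.6% with total counts, 53.3% with DESeq2 and 61.3% after the GC correction.

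In the knockout line, 339 of 574 miRNAs passed, 191 higher and 148 lower in EVs. miR-4516 (5.75, SE 0.24) and miR-1246 (3.95, SE 0.20) were higher in EVs as in the other lines, and so were miR-454-3p (3.43, SE 0.12) and miR-16-5p (2.28, SE 0.12). Of miRNAs with no count in knockout cells, miR-223-3p was at least 15-fold, miR-411-5p at least 14.5-fold, miR-494-3p at least 9.21-fold, miR-144-5p at least 8.16-fold and miR-122-5p at least 6.71-fold higher in EVs; the call of miR-144-5p was lost without knockout EV replicate 1 (fitted value 3.89). miR-4521 (−4.79, SE 0.24), the hypoxia-induced miR-210-3p (−3.38, SE 0.16), miR-138-5p (−2.29, SE 0.13), miR-193b-3p (−2.21, SE 0.23) and miR-874-3p (−1.97, SE 0.16) were lower in EVs. No fixed list passed the camera test in this line.

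Averaged over the 3 lines with equal weight, 247 of 574 miRNAs passed, 124 higher and 123 lower in EVs. At 4-fold or more, 37 were higher and 17 lower. Named here are called miRNAs at or above the median mean level whose EV and cell libraries did not overlap. Of these the highest were miR-451a (log2 fold change 8.01, SE 1.22, adjusted p = 0.00141), miR-4488 (6.16, SE 0.23), miR-379-5p (5.78, SE 0.72), miR-4516 (5.64, SE 0.20), miR-1246 (5.28, SE 0.12, adjusted p = 9.34e-39), miR-6087 (5.08, SE 0.17), miR-143-3p (4.56, SE 0.21), miR-4485-3p (2.66, SE 0.22) and miR-23a-5p (1.26, SE 0.11). let-7d-5p rose less, by 0.89 (SE 0.07), and so did miR-181b-5p, by 0.45 (SE 0.07), which did not pass without filtering (0.18). Of the same set miR-4521 was the lowest (−4.90, SE 0.16, adjusted p = 1.04e-31), and miR-3940-3p (−2.01), miR-132-5p (−1.23), miR-941 (−1.18), miR-331-3p (−1.17), miR-24-2-5p (−1.13) and miR-423-3p (−1.12) were lower too. miR-28-3p (−0.98), miR-671-3p (−0.95), miR-99b-5p (−0.87), miR-1307-3p (−0.69), miR-589-5p (−0.66), miR-30e-5p (−0.40) and miR-30d-5p (−0.38) were lower by less, and the last 2 did not pass with total counts (−0.13 and −0.10). The list of annotated fragments of other RNAs had 13 of 23 entries higher and 2 lower (13 and 2 adjusted over the list alone; camera adjusted p = 0.0123, adjusted p = 0.109 with an estimated correlation, and 0.0566 with total counts and the preset one). In the control line 15 of its 23 were higher and 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 0.00486, adjusted p = 0.0758 with an estimated correlation). The mean over lines also passed for 14q32 (7 of 38 higher; camera adjusted p = 8.07e-14, adjusted p = 0.0563 with an estimated correlation), the blood list (6 of 10; 2.06e-04, and adjusted p = 0.364 with an estimated correlation) and stroma (1 of 8; 0.00288, and adjusted p = 0.109 with an estimated correlation), with the same counts adjusted over each list alone. With miRNAs at 0 set to their bounds, control line medians were 7.05 for 14q32, 8.85 for the blood list and 6.67 for stroma. The same medians were 0, 0.0471 and −0.314 in the knockdown line and 2.77, 2.82 and 1.67 in the knockout line. In the knockdown line no 14q32 or blood entry met the rule for a bound. The median of 0 for 14q32 reflects members with few or no counts in both fractions, so it does not measure enrichment in EVs. Summed, 14q32 held 1916 CPM ± 78.5 in control EVs against 0.919 ± 0.106 in control cells, 38.8 ± 3.29 against 1.9 ± 0.441 in the knockdown line and 13.5 ± 6.97 against 1.86 ± 0.822 in the knockout line (SD, n = 2 each). The knockdown values rest on 6 and 7 counts in EVs and 7 and 5 in cells. Stroma held 3892 CPM ± 60.1 against 21.1 ± 1.32, 113 ± 2.76 against 14.9 ± 2.31 and 47.5 ± 10 against 13.6 ± 2.02 in the same order (SD, n = 2 each). Without the knockdown line 382 miRNAs passed. Higher ones made up 50.2% of the calls, against 71.7% with total counts and 61.9% with DESeq2.

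Whether a line's difference from control was itself different between EVs and cells was tested as an interaction. For the knockdown, 107 of 574 miRNAs passed, 25 with a higher and 82 with a lower change in EVs than in cells. miR-122-5p changed by −8.26 (SE 0.50, adjusted p = 3.82e-19), as it rose in knockdown cells and fell in knockdown EVs, and miR-34c-5p changed by 1.35 (SE 0.19, adjusted p = 1.21e-07). The interaction was lower for 14q32 (4 of 38; camera adjusted p = 4.69e-17, adjusted p = 0.0318 with an estimated correlation), the blood list (3 of 10; 1.02e-04, and adjusted p = 0.455 with an estimated correlation) and stroma (4 of 8, 5 adjusted over the list alone; 1.02e-04, and adjusted p = 0.0436 with an estimated correlation); the first 2 counts did not change when adjusted over the list alone. Limma-voom passed 205 miRNAs. Higher ones were 23.4% of the calls, against 52.6% with total counts, 33.6% with DESeq2 and 56.7% after the GC correction.

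For the knockout, 277 of 574 miRNAs passed the interaction, 143 with a higher and 134 with a lower change in EVs than in cells. miR-590-3p (5.21, SE 0.33), miR-335-3p (5.09, SE 0.25), miR-374b-3p (4.26, SE 0.33), miR-454-3p (4.12, SE 0.16, adjusted p = 3.37e-27) and miR-374a-3p (3.80, SE 0.19) fell in knockout cells and not to that extent in knockout EVs. Of 239 such miRNAs tested in both fractions, 147 had passed in cells alone, 22 in EVs alone, 65 in both and 5 in neither. The miR-15/16 family followed the first pattern, with 9 of 11 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 8.69e-04, adjusted p = 0.238 with an estimated correlation). Of the miR-200 family 3 of 6 were higher (3 adjusted over the list alone; camera adjusted p = 0.0493, adjusted p = 0.275 with an estimated correlation, and 0.051 with RLE size factors and the preset one). The interaction was lower for 14q32 (13 of 38, 12 adjusted over the list alone; camera adjusted p = 8.43e-20, adjusted p = 0.0208 with an estimated correlation), stroma (8 of 8, also 8 adjusted over the list alone; 1.36e-04, and adjusted p = 0.0468 with an estimated correlation) and the blood list (6 of 10, also 6 adjusted over the list alone; 1.05e-04, and adjusted p = 0.275 with an estimated correlation). miR-122-5p could not be read in this interaction by edgeR (adjusted p = 0.942), since knockout cells had no count of it, although DESeq2 (−3.97) and limma-voom (−4.91) passed it.

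The 2 modified lines share their control libraries, so their log2 fold changes correlate by chance alone. In cells the correlation across 613 miRNAs was 0.0736 (Spearman rho 0.14) with a covariance of 0.235, against a mean correlation of 0.286 and a mean covariance of 0.0761 in 20 simulations with no effect. In these cells 47 miRNAs were higher in both lines, against 41.3 for independent lists, 90 were lower in both, against 62.6, and 99 went in opposite directions. In EVs the correlation across 488 miRNAs was 0.652 (rho 0.268) with a covariance of 4.85, against 0.0676 and 0.0338 in simulations, and 22 miRNAs were higher in both against 17.3 for independent lists, 58 lower in both against 29.9, and 43 opposite. The 2 control libraries per fraction were not split, since each part would keep 1. In EVs the shared falls included members of the blood and stroma lists and the imprinted cluster. These lists stood higher in control EVs than in any other group, at 10710, 3892 and 1916 CPM. Knockdown EVs held 217, 113 and 38.8 CPM of them, and knockout EVs 192, 47.5 and 13.5. A high level in control EVs alone gives such falls, so they do not show a response common to the 2 lines. Part of the remaining excess may also come from the shared controls. Between fractions no library is shared: the change in cells and the change in EVs correlated at 0.55 (rho 0.563) across 430 miRNAs for the knockdown, with 65 higher in both, 68 lower in both and 12 opposite. For the knockout the correlation was 0.40 (rho 0.325), with 47 higher in both, 30 lower in both and 36 opposite. Independent lists would give 23.6 higher and 35.9 lower in both for the knockdown, and 29.1 and 23.5 for the knockout. miRNAs are not independent replicates, so no p-value is given.

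**Figure D4:**
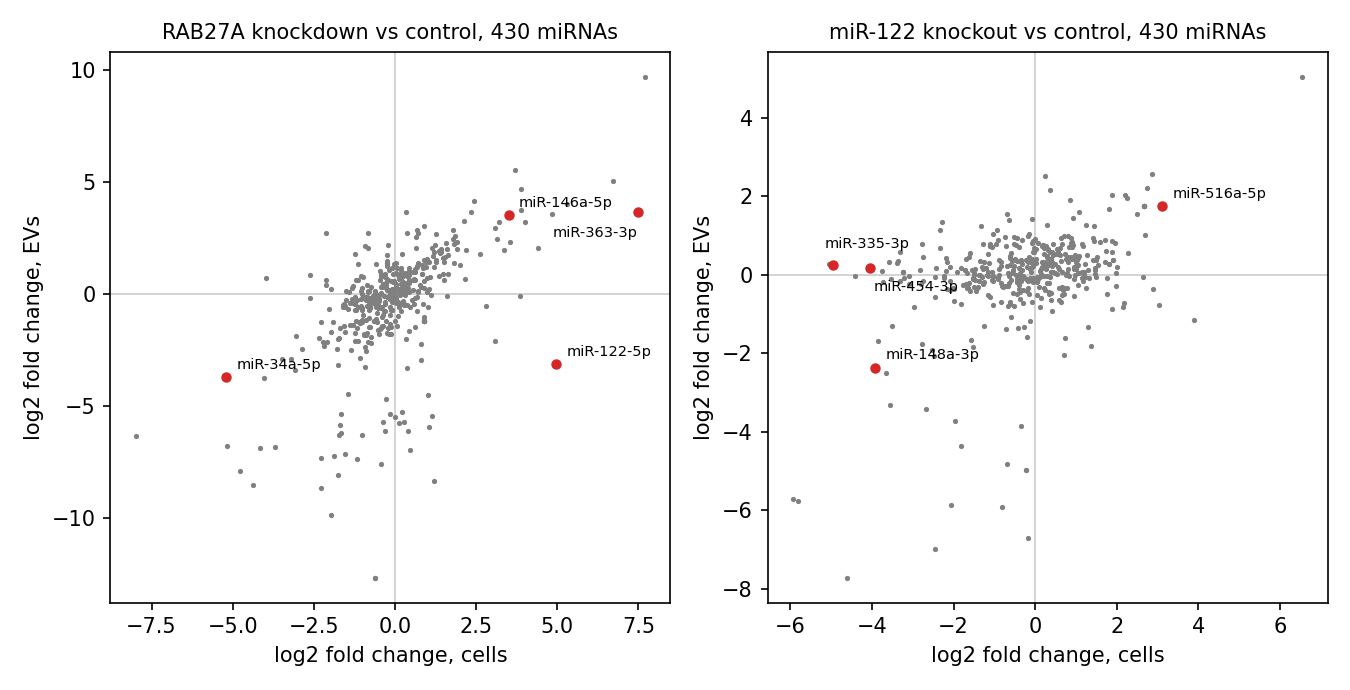
Log2 fold change against control in cells (horizontal axis) and in EVs (vertical axis) for the RAB27A knockdown on the left and the miR-122 knockout on the right, over 430 miRNAs tested in both fractions, with 4 named miRNAs per panel in red; values of miRNAs with no count in a group are fitted ones. The Pearson correlation is 0.55 on the left and 0.40 on the right, where miR-454-3p lies at −4.05 in cells and 0.17 in EVs.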

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

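Of the tests below, those of the blood-cell list in control EVs, of miR-122-5p against that list, of depth by thinning cells and EVs alike and of the GC correction on the interaction calls were chosen only after the result was seen, and so were the comparison with miR-451a and the splits of whole groups; the others were set out before, but the readings of the GC correction and of the comparison of the 2 modified lines for the raised clusters depart from bounds set in advance, and the number given for miR-122-5p in knockout EVs was changed from a p-value to a predicted count after its value was seen, and a depth test set out before was dropped after its value was seen, since it thinned cell libraries of similar depth and could hardly have changed the calls, and a test of constant export of the blood list, itself chosen after the result was seen, was dropped because it restated the first pattern.

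In 107 miRNAs the change of the RAB27A knockdown line against control differed between EVs and cells, by the interaction test. The named ones were miR-122-5p (log2 −8.262), miR-4521 (2.272), miR-3065-3p (1.997), miR-365a-3p and miR-365b-3p (1.429 each, with identical counts), miR-34c-5p (1.35), miR-199a-3p and miR-199b-3p (−13.39 each), miR-26a-2-3p (−9.252) and miR-411-5p (−8.929). Values for miR-199a-3p, miR-199b-3p and miR-26a-2-3p depend on the prior count, since knockdown EVs held none of them. That of miR-411-5p rests on few counts, with 4 in control cells, 4 in knockdown cells and 1 in knockdown EVs. The call of miR-4521 was lost without filtering (2.61), without the 5 most abundant miRNAs (2.15) and on leaving out 10 of the 12 libraries one at a time, with values of 1.82 (without control EV replicate 2) to 2.57 (without knockdown EV replicate 2). Without knockdown EV replicate 1 the call of miR-3065-3p was lost (0.50), as it was without knockdown cell replicate 2 (1.54). The call of miR-26a-2-3p was lost without either knockdown EV library (−9.12 in both cases), and that of miR-411-5p without knockdown cell replicate 2 (−4.26).

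In 277 miRNAs the change of the miR-122 knockout line differed between EVs and cells. The named ones were miR-590-3p (5.21), miR-335-3p (5.093), miR-374b-3p (4.264), miR-454-3p (4.124) and miR-374a-3p (3.802) on the higher side, and miR-144-3p (−9.471), miR-127-3p (−8.502), miR-150-5p (−8.323), miR-451a (−8.245) and miR-379-5p (−7.585) on the lower. Control cells held no count of miR-150-5p and 3, 2 and 3 of miR-144-3p, miR-127-3p and miR-379-5p, so these 4 values depend on the prior count or on few counts. Without filtering miR-144-3p (−9.47) and miR-451a (−8.24) no longer passed. Leaving out a cell library also ended some calls: miR-144-3p without control cell replicate 1 (−9.84), control cell replicate 2 (−9.12) or knockout cell replicate 2 (−4.88), miR-150-5p without knockout cell replicate 2 (−6.45), and miR-451a without control cell replicate 1 (−7.60) or knockout cell replicate 2 (−6.21).

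The first pattern is that control EVs held blood-cell and stroma miRNAs together with miR-122-5p, at levels that neither their cells nor the EVs of the other lines reached, with a median log2 fold change of −6.9 for the blood list in knockout EVs over control EVs (−6.61 with bounds). RNA from blood or serum in the control EV preparations is a candidate explanation that the data prompted and cannot bear out: the blood list had a median of 9.54 over control cells (8.85 with bounds), with a list test that passed with the preset correlation and not with an estimated one (adjusted p = 0.184); other organs' lists gave no decision, with medians of 6.67 for stroma, 2.96 for muscle and −0.515 for the nervous system, of whose 6 tested entries control cells held 3 at 10 CPM or more. Such RNA at the control EVs' ratio does not account for miR-122-5p in knockdown EVs, which held 12 counts against a predicted 1.98 (exact one-sided p = 2.58e-06), whereas for the 7 counts in knockout EVs the list predicted 36.6 (25 to 49) and miR-451a 10.6 (5 to 17), and this cannot be told apart from other sources, because the list's 192 CPM ± 48.2 in knockout EVs (SD, n = 2) differ from the 169 ± 2.05 of knockout cells by less than that SD, although its median over those cells was 3.05 (2.82 with bounds). The labels give all 3 lines the same albumin, conditioning time and spins, and the list summed to 10710 CPM in control EVs against 217 and 192 in the other EVs. Release of blood-type miRNAs by the control line alone, as a difference between the lines in the design, was not tested and stays open.

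The second pattern is that many miRNAs changed in knockout cells without a like change in knockout EVs, with a median size of 1.31 in cells and 0.354 in EVs on the log2 scale over 239 miRNAs of the interaction. Without the 5 most abundant miRNAs, 97% of the calls in knockout cells still tested were kept, above the bound of 80% set in advance. TMM factors already limit the weight of dominant miRNAs, so this test could hardly have come out otherwise. A take-over by a few miRNAs stays open, as miR-100-5p held 49.5% and 45.6% of the counts in knockout cells against 33.5% and 31.7% in control cells. Library depth stays open in part: with the control and knockout libraries of both fractions thinned to 2387336 counts, 71.4% to 75.6% of 266 interaction calls were kept in 10 draws, and 77.6% to 82% of those still tested, where over 80% in every draw would argue against it. After a GC correction 230 of 277 interaction calls were kept (83%, SE 2.26 over miRNAs, which are not independent), against a bound set after the result. Most interaction calls thus did not hang on a smooth trend with the GC content of the hairpin side. The correction does not cover the mature sequence or other forms of bias, so GC-dependent recovery stays open. In knockout cells the rank correlation of 0.418 with GC content went down to 0.0791 and 313 of 382 calls were kept (81.9%, SE 1.97). That share exceeds the bound of 80% set in advance by less than the standard error. Loss of miR-122 as the cause was not tested apart from these, since the knockout is a single line.

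The third pattern is the rise of 2 clusters, miR-106a-363 and let-7c with miR-99a and miR-125b-2, in knockdown cells. Reads shared with near-identical relatives were weighed on 4 members taken to lack such relatives. All 4 passed with a median log2 fold change of 7.09 (SE 0.971, or 5.97 with miRNAs at 0 set to their bounds). The SEs of medians in this paragraph run over members of 2 clusters, which are not independent. Other such members were not tested, and the filter keeps miRNAs that are high in a single group, which favoured this outcome in advance. Control and knockdown cells held 2 and 16 counts of let-7c-3p and 0 and 31 of miR-99a-3p. The rises of miR-363-3p (21 counts in control cells, 1040 in knockdown cells) and miR-125b-2-3p (23 and 663) argue against shared reads for those members alone. The 9 members had a median of 4.63 over control in knockdown cells and −0.717 in knockout cells, and 5.02 (SE 1.69) between the 2 lines, a fitted value that rests in part on 3 miRNAs with no count in knockout cells. That difference exceeds the bound of 2 SE set in advance against a difference between cell lines, but the bound was wrong for this design, because it excludes only a difference that both modified lines share and a change private to the knockdown line gives the same value. With 1 knockdown line, an effect of RAB27A loss and a change private to that line, such as a clone or an integration, cannot be told apart.

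For EVs against cells over the 3 lines, the 12 libraries were also split at random into 6 and 6, with 100 of 462 splits drawn. In a model with these groups alone the real split gave 40 miRNAs, and 2 splits, the real one included, gave as many, which excludes chance only for libraries taken singly, as most splits part the replicates of a group. The highest other drawn split gave 62, with control cells, knockdown cells and knockdown EVs on one side. Of the 10 splits that keep groups whole, too few for a share under 0.05, 4 with the real one gave as many and the highest gave 94, with the control cells and the control and knockout EVs on one side, which points to a structure of the samples beyond fraction.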

How the results depend on the processing

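Of the alternatives below, the restriction to miRNAs at 10 CPM or more in a cell group, thinning, the mean without a line and the GC correction were chosen only after the result was seen. The number of passing miRNAs stayed within 1.5 times for all 10 comparisons with RLE size factors, total counts, DESeq2, no filter, the stricter filter, the GC correction and without fragments of other RNAs. Over the miRNAs the text names, 4317 values under an alternative stayed on their side of the threshold, 54 no longer passed and 15 came to pass. None had the opposite sign with a pass in either fit. A change of sign where neither fit passed was not counted, and miRNAs not tested under an alternative were left out. The text names only part of what the naming rule takes, and the rest was less stable. Of 18006 values of 819 further pairs of a miRNA and a comparison, 16185 stayed on their side of the threshold with no counted change of sign. Of these pairs 71 had the opposite sign under some alternative with a pass in 1 of the 2 fits, most often with total counts (29 of 83 values). In 5 pairs both fits passed in opposite directions, 4 of them in the mean over lines without the knockout line. Leaving out single libraries gave 196 to 385 miRNAs for the knockdown in cells and 127 to 205 for the knockout in EVs, the lowest without knockdown cell replicate 1 and without control EV replicate 2; the cause was not tested. A lone sample left in a group was assumed to vary like the other groups. Restriction to miRNAs present in cells left 127 for the knockout in EVs and 180 for control EVs over cells, as fewer miRNAs were tested. Thinning left 137 for the knockdown and 76 for the knockout in EVs. It cut mainly the control and knockout EV libraries, since the knockdown EV libraries were already the shallowest. These counts therefore do not measure what depth costs the knockdown EVs. Limma-voom gave 215 for EVs over cells in the knockdown line and 205 for its interaction, and leaving out the 5 most abundant miRNAs gave 177; the cause was not tested. The mean over lines without the knockdown line gave 382; the cause was not tested. TMM-scaled miR-122-5p was 13.21 CPM in knockdown cells and 1.094 in knockout EVs, as scaling alone moves it. List tests passed 6 times with an estimated correlation against 34 with the preset one, and the cause was not tested. Total counts ended 3 list calls and made 3, and RLE factors ended 1 and made 2, none with the opposite direction.

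The correlation of the 2 lines' changes in cells was 0.0205 with the stricter filter and 0.0184 to 0.149 without single libraries; in EVs it was 0.566 to 0.646 without single libraries. The correlation of cell and EV change was 0.716 for the knockdown and 0.517 for the knockout with the stricter filter, which tests fewer miRNAs. Without single libraries it was 0.478 to 0.58 and 0.337 to 0.404; the cause was not tested.

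The replicate numbers share only a number: deviations of same-numbered libraries correlated at −0.204 to 0.22 over 329 miRNAs. With the replicate block the 10 comparisons gave counts each within 1.5 times, such as 319 and 377 for the knockdown and knockout in cells, 211 and 181 in EVs, 246 for the mean over lines and 116 and 269 for the interactions. It moved miR-4521 (2.271) in the knockdown interaction and the miR-200 family (adjusted p = 0.0595) in the knockout interaction past the threshold to the side of no call, and C19MC to a call in EVs over cells of the knockdown line (adjusted p = 0.0441). Another scaling moved the median of all miRNAs by over 0.1 on the log2 scale. With total counts it moved by −0.339 and −0.374 for the knockout in cells and EVs, 0.116 for the knockdown in EVs, 0.139, 0.294, 0.204 and 0.271 for EVs over cells in the control, knockdown and knockout lines and their mean, and 0.326 for the knockdown interaction. With RLE factors it moved by 0.116 and −0.101 for the knockdown in cells and the knockout in EVs, 0.102 for EVs over cells in the knockdown line and −0.146 for the knockout interaction.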

Other observations

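The 3 miRNAs named in this part, the comparison of knockout with knockdown EVs, and the comparison each list is described in were chosen only after the result was seen, while the lists were fixed before the data were examined.

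miR-887-3p was near the floor in the control line and present in both modified lines. Control cells held 1 count, knockdown cells 78 and knockout cells 88, a 284-fold higher share in knockdown cells (95% counting interval 49.4 to 11300) and a 101-fold higher share in knockout cells (17.6 to 4020). Control EVs held none, and miR-887-3p was at least 104-fold higher in knockdown EVs (adjusted p = 3.48e-06) and at least 2.82-fold higher in knockout EVs (adjusted p = 0.0061) by edgeR's quasi-likelihood test. The call in knockout EVs was lost without control EV replicate 1 (fitted value 4.90), control EV replicate 2 (4.88) or knockout EV replicate 1 (4.41). miR-105-5p and miR-767-5p, neighbours on the X chromosome, rose in knockdown cells and did not pass in knockout cells: the share of miR-105-5p was 221-fold higher (74.3 to 1080; adjusted p = 1.04e-11) and that of miR-767-5p 275-fold higher (74.7 to 2290; adjusted p = 4.34e-11) than in control cells, where they had 3 and 2 counts. In knockout cells the 2 miRNAs had 1 and 0 counts.

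The remaining lists did not pass the camera test in any of the 10 comparisons. In knockdown cells 6 of 7 tested members of the miR-29 family fell and none rose (6 adjusted over the list alone; camera adjusted p = 0.0637, adjusted p = 0.61 with an estimated correlation). Of 20 let-7 members 4 rose and 10 fell there (4 and 11 adjusted over the list alone; adjusted p = 0.761, and 0.928 with an estimated correlation). Of 7 members of the miR-34 and miR-449 family 1 rose and 5 fell (2 and 5 adjusted over the list alone; 0.19 and 0.522). Of the cluster of miR-183, miR-96 and miR-182, 3 of 5 fell (3 alone; 0.231 and 0.61), and of the miR-17-92 clusters 5 rose and 8 fell of 21 (5 and 8 alone; 0.875 and 0.928). In knockout cells 6 of 8 members of the miR-130 and miR-301 family fell and 1 rose (6 and 1 alone; 0.142 and 0.473), and of the miR-148 and miR-152 family 4 of 6 fell and 1 rose (4 and 1 alone; 0.107 and 0.611). Of the miR-99/100 and miR-125 family 6 of 11 rose and 2 fell in those cells (6 and 2 alone; 0.186 and 0.607). In knockout EVs 8 of 11 members of the miR-23/24/27 clusters rose and 1 fell (8 and 1 alone; 0.0541 and 0.364), and of the miR-30 family 4 of 11 rose and 1 fell (4 and 1 alone; 0.185 and 0.604). In control EVs over control cells 3 of 6 nervous system entries were lower and none higher (3 alone; 0.17 and 0.545), and both muscle entries were higher, too few for the list test. The X-linked miR-506 cluster had 1 tested member, which rose in knockdown cells.

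Knockout and knockdown EVs, compared without the control libraries in the contrast, differed in 197 of 488 miRNAs, 111 higher and 86 lower in knockout EVs.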
